A study of Homo sapiens with 9 samples.

How the data were processed

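Total RNA was measured in 9 libraries of the human melanoma line 501mel, 24 h after lipofection with a control DsiRNA (NC1) or with DsiRNA 13.6 or 13.8 against TBX3. Each group has 3 libraries, called biological replicates in the labels, and the library kit keeps strand information. Per the submitters' processing notes, cutadapt, FastQC, STAR, HTSeq, DESeq2 and the build hg19 were used; their versions, the gene annotation and the strand setting of the counting are not given in the sources used here. The deposited count table holds raw counts of reads per gene symbol, and every value in it is a whole number. The deposited normalized table, made by the authors, holds log2 values of the count divided by a size factor of the library, plus 1. For the 25378 genes compared, these log2 values of the authors gave back the counted reads with a largest deviation of 0.00203 of a read, and all tests were run on the raw counts.

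The count table holds 25398 entries. Left out were 16 that repeat a symbol with the same counts, which leaves 25382, of which 3249 have no reads. Another 28 entries carry names that a spreadsheet turned into dates; they hold 0.200% of the counts, were kept in the totals and are not named. Symbols are given as in the table, some of them older names: DDX58 is now RIGI, CTGF CCN2, CYR61 CCN1, ATP5F1 ATP5PB, and ND2, ND3, ND1 and ATP8 carry the prefix MT-. No genome positions are given, since the counts rest on hg19 and the reference at hand is GRCh38, which was used only for gene biotypes and transcript sequences.

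Library totals ran from 38105026 to 52272147 counted reads. Replicate libraries of a group had Pearson correlations of 0.991 to 0.995 across genes on the log2 CPM scale, and libraries of different groups 0.964 to 0.978. Replicates varied more than counting error alone, with a chi-square per degree of freedom of 5.01 to 43.2, so that all tests use the spread between replicates. The first principal component took 48.9% of the variance and the second 28.3%.

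Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with its preset of at least 10 reads, which left 14731 genes with 99.97% of the reads, and libraries were scaled by TMM. A quasi-likelihood model with robust spread estimates was fitted to all 9 libraries with 1 mean per group, leaving 6 residual degrees of freedom. The comparisons are each DsiRNA against control, the mean of both against control, and 13.6 against 13.8, each two-sided. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the 14731 genes. SEs come from the same model. A fold change of a gene with few reads is also given as a ratio of reads scaled by library totals, with its exact 95% interval, which holds counting error only.

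Gene lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the lists with at least 5 tested members, 26 of 29. Camera compares a list with all other genes. The lists cover melanin and melanosome genes, pheomelanin and cysteine-glutathione genes, MC1R and cAMP-CREB signalling, the MITF programme, the undifferentiated and neural crest-like melanoma state, epithelial-mesenchymal and adhesion genes, reported targets of TBX3 repression, the T-box family, WNT-beta-catenin targets, MAPK-ERK output, p53 targets, S phase, G2 and M phase, interferon-stimulated genes, NF-kB and inflammatory cytokines, the integrated stress response, the unfolded protein response, NRF2 targets, cholesterol and fatty acid synthesis, glycolysis and hypoxia, nuclear oxidative phosphorylation, mitochondrially encoded genes, cytosolic ribosomal proteins, apoptosis regulators, the small RNA pathway, and markers of fibroblasts, keratinocytes, leukocytes and endothelium. The lists were written from general knowledge, and none was chosen on these samples.

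The comparisons, lists, tests, thresholds, the rule for named genes and all but 2 of the alternatives were chosen before the data were examined. The tests that weigh explanations in the closing section were set afterwards. The named genes are TBX3; for each DsiRNA the 6 higher and 6 lower genes with the largest change among those called, with a mean of at least 5 CPM and all 3 knockdown libraries beyond all 3 controls; the 10 higher and 10 lower with the largest smaller change of both DsiRNAs, all 6 knockdown libraries beyond the 3 controls; the 5 higher and 5 lower between the DsiRNAs; up to 4 members of each list with the smallest adjusted p in the comparison, and members that went against their list; and 18 genes fixed in advance. The rules by size skip clone and locus names and pseudogenes. Some of the genes these rules give are not reported here. By chance alone all 3 libraries of a group lie beyond the 3 of another in 10% of genes, 5% in each direction.

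The alternatives are DESeq2 1.42.0, limma-voom, DESeq2 size factors or library totals in place of TMM, no filter or at least 50 reads on average, an adjusted p under 0.01, a fold of at least 2, glmTreat against a 1.2-fold change, only the compared libraries in the fit, the replicate number as a block, each library left out in turn, and, for lists, an estimated correlation and fry. Fits of other splits of the libraries, and 20 simulations in which nothing changed but the controls were shared, were run for the closing section.

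The search for words was chosen after the data were examined. Log2 fold changes, with extreme values limited, were first adjusted for the length and GC content of the 3′ UTR. In the 3′ UTRs of 12374 tested genes (84.0%), 14399 words of 7 bases held by at least 100 genes were searched. In a random part of the genes, the mean adjusted value of genes with a word was compared with that of the others by a t statistic. The words with the lowest t with each DsiRNA and the highest with both were taken. Each was tested on the adjusted values of the other 6187 genes with 10000 permutations, which can give no p under 0.0001. The permutations shuffle genes of the same 9 libraries, which are not independent, so the p leaves out the spread between libraries. Differences of held-out carriers are given on this adjusted scale. The sequences of the DsiRNAs are not given in the sources used here. The other 2 alternatives chosen after the data were examined leave out genes with any of these 3 words, and correct for GC content and transcript length.

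The methods were tested on simulated data. For DsiRNA 13.6 against control, among 14731 genes drawn with the spread seen here, the edgeR test called 44 of 67 genes changed 1.5-fold (65.7%), 53 of 67 changed 2-fold (79.1%) and 60 of 66 changed 4-fold (90.9%), and 11 of 14531 unchanged genes (0.0757%). The median estimated folds were 1.50, 2.05 and 4.05. Far fewer genes changed there than the 7357 called in the real comparison. With the adjusted p used, the rates of right and false calls depend on that share and do not carry over. The list test called the 1 list of 35 genes shifted 1.3-fold and 0 of the 25 others. Genes were drawn independently there, so this does not cover lists whose members move together. In the real libraries, splits that mixed the groups called up to 11 lists. The word search found 20 of 20 planted words and gave p under 0.01 in 1 of 20 runs with none. Values were summarised with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and drawn with matplotlib 3.10.9.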

Results

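RNA was sequenced from 501mel cells, an established human melanoma line, harvested 24 h after lipofection with a DsiRNA, a short synthetic RNA that Dicer processes into a silencing guide. Cells received the control DsiRNA NC1 or 1 of 2 DsiRNAs against TBX3, named 13.6 and 13.8, and each group held 3 biological replicates, 9 libraries in all. The series asks what TBX3, a T-box transcription factor, does in pigment cells that have lost signalling through MC1R, the melanocortin receptor that sets the balance of dark eumelanin to red-yellow pheomelanin. The control libraries held 45386350, 38105026 and 41206642 counted reads, the 13.6 libraries 41592157, 47531852 and 46623785, and the 13.8 libraries 47137721, 52272147 and 48567562. Of the genes counted, 14731 were tested. Levels are given as CPM, a gene's reads scaled by its library's total times its TMM factor, as mean ± SD over n = 3 libraries, and log2 fold changes as estimate ± SE. "Rose", "fell" and "changed" refer to an adjusted p under 0.05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment for a gene, and by camera for a gene list.

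TBX3 itself was lower in each of the 6 knockdown libraries than in any control library. The controls gave 88.64, 83.80 and 84.02 CPM, the 13.6 libraries 46.4, 41.0 and 39.4 CPM, and the 13.8 libraries 36.1, 33.7 and 36.2 CPM. TBX3 fell by 50.6% with DsiRNA 13.6 (log2 fold change −1.02 ± 0.07, adjusted p = 1.3e-07 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment) and by 58.6% with DsiRNA 13.8 (−1.27 ± 0.07, adjusted p = 1.0e-08 by the same edgeR test). The level with 13.6 was higher than with 13.8 by 0.26 ± 0.07 (adjusted p = 0.0070 by the same edgeR test).

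**Figure D1:**
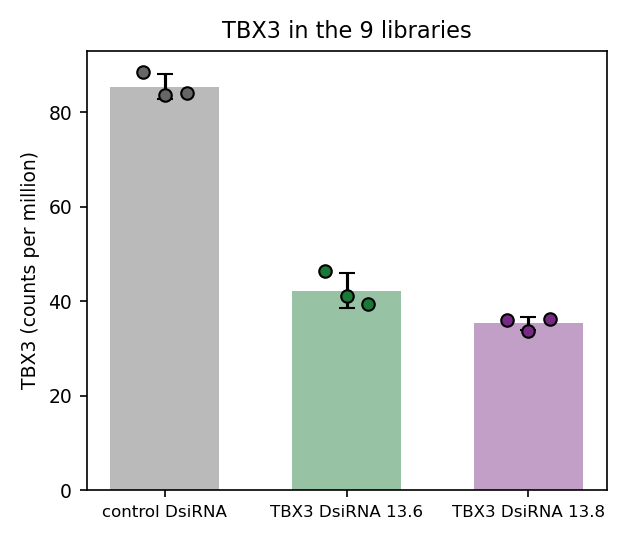
TBX3 in CPM for the control DsiRNA and the 2 TBX3 DsiRNAs, with points for the 3 libraries of each group, bars for the group mean and error bars for the SD. The control libraries lie between 83.8 and 88.6 CPM and the 6 knockdown libraries between 33.7 and 46.4 CPM.

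DsiRNA 13.6 against control asks what follows a loss of about 50.6% of TBX3 mRNA with 1 reagent. Among genes with a mean of at least 5 CPM the largest rises were those of NEK7, a kinase of mitosis and of the NLRP3 inflammasome (9.49-fold, 21.2 ± 0.7 to 201 ± 6.7 CPM, log2 fold change 3.25 ± 0.06), and SESN3, a sestrin that restrains growth signalling (3.03 ± 0.09, from 9.8 ± 1.1 to 79.5 ± 1.2 CPM). PCLO, a presynaptic scaffold protein (2.98 ± 0.08), ACSL5, which activates long-chain fatty acids (2.95 ± 0.11), the B-cell survival cytokine TNFSF13B (2.94 ± 0.17) and the interferon-induced oligoadenylate synthetase OAS1 (2.88 ± 0.15) followed. Under the same floor the largest falls were those of DHRS2, a short-chain dehydrogenase (−2.97 ± 0.29), ATP6V1E1, a subunit of the vacuolar proton pump (361 ± 23.7 to 46.8 ± 1.1 CPM, −2.95 ± 0.07), and MLIP, a lamin-interacting protein of muscle (−2.82 ± 0.20). MS4A15 (−2.70 ± 0.21), UBAP1L (−2.69 ± 0.20) and FHL2, a LIM-domain coactivator (−2.56 ± 0.09), fell as well. All 3 knockdown libraries lay beyond all 3 controls in these 12 genes by the rule that chose them, so this is not a result. The 3′ UTRs of ATP6V1E1, MS4A15 and FHL2 hold the 7-base word GCTCTGT, and those of NEK7 and TNFSF13B the word GATTAAC. Of all 12374 searched genes 20.9% hold GCTCTGT and 5.89% hold GATTAAC. A word held by a single gene describes that gene and does not show why it changed. In a search of 14399 such words, GCTCTGT had the lowest t statistic with 13.6. In 6187 genes held out of the search its carriers were 0.147 lower on the log2 scale than other genes (permutation p = 0.0001, the smallest that 10000 permutations can give). The values compared were adjusted for the length and GC content of the 3′ UTR. This and the other permutation p-values of words treat genes as independent and leave out the spread between libraries.

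Among pigment-cell genes, TYR, the rate-limiting enzyme of melanin synthesis, rose from 380 ± 17.8 to 808 ± 11.9 CPM with 13.6 (1.09 ± 0.07). TYRP1 and DCT, which act after TYR in eumelanin synthesis, fell by 0.42 ± 0.06 and 0.49 ± 0.10 on the log2 scale, and OCA2, a melanosomal transporter, fell by 1.51 ± 0.12. TRPM1, the host gene of a melanocyte microRNA, fell by 2.32 ± 0.15, and RAB38, which carries melanosome enzymes, by 0.83 ± 0.07. Of the 30 melanin and melanosome genes 3 rose, 15 fell and 12 did not pass the test, with a median of −0.17 (camera adjusted p = 0.0577). MC1R rose by 0.38 ± 0.08 and SOX10, a neural crest transcription factor, by 0.32 ± 0.07, while MITF, the master regulator of melanocytes, stood at −0.04 ± 0.11 and the melanosome fibril protein PMEL at 0.08 ± 0.08. The MITF programme split, with 9 of 33 measured genes higher, 8 lower and 16 not past the test (median 0.02, camera adjusted p = 0.815). Within it VAT1 (−1.41) and the transporter ABCB5 (−1.50) fell and the sialyltransferase ST3GAL6 (1.07) rose. The melanocyte antigen MLANA fell by 0.20 ± 0.07 and the cystine importer SLC7A11 by 0.23 ± 0.07. The MLANA call was lost without control replicate 2 (−0.20) or 3 (−0.15) or 13.6 replicate 1 (−0.18) or 2 (−0.19). The SLC7A11 call was lost without control replicate 1 (−0.16) or 13.6 replicate 2 (−0.21) or 3 (−0.21). The 3′ UTRs of TYRP1 and MLANA hold GATTAAC, and those of OCA2, RAB38 and SLC7A11 the 7-base word AACTGTC, which 11.1% of all searched genes hold.

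The pheomelanin and cysteine-glutathione list, which covers the supply of cysteine for pheomelanin, fell: 12 of 22 genes were lower, 3 higher and 7 not past the test (median −0.30, camera adjusted p = 0.0236, and adjusted p = 0.256 with an estimated correlation). MFSD12, a cysteine importer of melanosomes (−2.17), GSR, which recycles glutathione (−1.07), CTH, which makes cysteine (−0.97), and the neutral amino acid transporter SLC1A4 (−0.91) fell, while GCLC, an enzyme of glutathione synthesis, rose by 0.48. NRF2 targets, genes of the oxidative stress response, were lower in 11 of 17 measured, higher in 1 and not past the test in 5 (median −0.36, camera adjusted p = 0.0022, and adjusted p = 0.256 with an estimated correlation). The thioredoxin reductase TXNRD1 (−0.60), the pentose phosphate enzyme PGD (−0.72), OSGIN1 (−0.77) and the quinone reductase NQO1 (−0.84) were among them. The integrated stress response and amino acid list fell, with 13 of 29 genes lower, 3 higher and 13 not past the test (median −0.17, camera adjusted p = 0.0278, and adjusted p = 0.727 with an estimated correlation). Its members ATF3, a stress-induced transcription factor (−0.86), PSPH of serine synthesis (−0.92) and PCK2 (−0.78) fell, whereas PSAT1, also of serine synthesis, rose by 2.29 ± 0.06. Without control replicate 3 neither the pheomelanin list nor the integrated stress response list passed (adjusted p = 0.0542 for each by camera). GSR, NQO1, PGD and PSPH hold GCTCTGT in their 3′ UTRs, TXNRD1 holds AACTGTC, and GCLC holds GATTAAC. MFSD12, CTH, SLC1A4, OSGIN1, ATF3, PCK2 and PSAT1 hold none of these words.

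Proliferation genes were lower with 13.6. Of 35 S-phase genes 26 fell, 3 rose and 6 did not pass the test (median −0.43, camera adjusted p = 9.95e-06, and adjusted p = 0.426 with an estimated correlation). They include the transcription factor E2F1 (−1.24), the ribonucleotide reductase subunit RRM2 (−1.14), CDC45 of the replicative helicase (−1.14) and HELLS (−1.06). Of 35 G2 and M-phase genes 23 fell, 3 rose and 9 did not pass the test (median −0.30, camera adjusted p = 0.0022, and adjusted p = 0.727 with an estimated correlation). BIRC5, also called survivin (−0.77), and the ubiquitin-conjugating enzyme UBE2C (−0.62) fell, while the kinetochore gene NUF2 (0.82) and the spindle gene HMMR (0.74) rose. NUF2 and HMMR hold GATTAAC, E2F1 holds GCTCTGT, and RRM2 holds both words. The cyclin-dependent kinase inhibitor CDKN1A was barely detected, with 36, 11 and 16 reads in the controls and 6, 5 and 11 with 13.6 (−1.56 ± 0.51). That fall did not pass the test without control replicate 1 (−1.03) or 13.6 replicate 1 (−1.48) or 2 (−1.32).

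Interferon-stimulated genes rose, with 24 of 33 measured genes higher, 3 lower and 6 not past the test (median 0.69, camera adjusted p = 1.0e-06, and adjusted p = 0.256 with an estimated correlation). IFIT3 (2.00), which holds GATTAAC, OAS1, the helicase DDX60 (1.46) and the RNA sensor DDX58 (1.47) were among the risers. Epithelial-mesenchymal and adhesion genes rose, with 15 of 24 measured genes higher, 4 lower and 5 not past the test (median 0.44, camera adjusted p = 0.0011, and adjusted p = 0.426 with an estimated correlation). Integrin ITGB1 (1.02), the transcription factor SNAI2 (0.96), the adhesion molecule MCAM (0.94) and the matrix protein SPARC (0.70) rose. Unfolded protein response genes rose, with 11 of 21 higher, 2 lower and 8 not past the test (median 0.22, camera adjusted p = 0.0414, and adjusted p = 0.296 with an estimated correlation). The chaperone HSP90B1 (0.999), PDIA6 (0.80) and DNAJB11 (0.59) rose and HYOU1 fell by 0.52. The list's call was lost without control replicate 2 (camera adjusted p = 0.0897) or 3 (camera adjusted p = 0.0542), or with a mean of at least 50 reads required (camera adjusted p = 0.0528). Nuclear oxidative phosphorylation genes fell, with 20 of 47 lower, 4 higher and 23 not past the test (median −0.18, camera adjusted p = 0.0278, and adjusted p = 0.907 with an estimated correlation). NDUFB10 of complex I (−1.58) fell, while ATP5F1 of the ATP synthase (1.24) and NDUFA5 (0.83) rose. That list did not pass without control replicate 3 (camera adjusted p = 0.287) or 13.6 replicate 1 (camera adjusted p = 0.106), or with genes holding any of the 3 words found in the search left out (camera adjusted p = 0.150).

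The other lists did not pass with 13.6. MC1R and cAMP-CREB signalling genes were higher in 7, lower in 11 and not past the test in 9 of 27 (median −0.03, camera adjusted p = 0.428), with falls of the phosphatase DUSP1 (−0.77), the mitochondrial coactivator PPARGC1A (−0.72 ± 0.08), the kinase subunit PRKAR1A (−0.57) and the nuclear receptor NR4A3 (−0.49). Genes of the undifferentiated and neural crest-like melanoma state were higher in 7 and lower in 9 of 21 measured (median −0.27, camera adjusted p = 0.634), with falls of LOXL2 (−2.88), CYR61 (−2.16), CTGF (−1.39) and JUN (−0.50). Of 5 reported targets of TBX3 repression 1 rose, the adhesion gene NCAM1 (0.40), 2 fell and 2 did not pass the test. CDH1, which encodes E-cadherin, stood at 0.38 ± 0.20 and CDKN2A at 0.32 ± 0.19. Among 8 T-box genes 3 rose, EOMES (1.98) and TBX15 (1.38) among them, and 3 fell, TBX2 (−0.51 ± 0.08) and TBX3 among them. ETV1 (1.19), EPHA4 (0.89), ETV5 (0.70) and DUSP4 (0.52) rose among MAPK-ERK output genes (8 higher, 3 lower of 21, median 0.01). FZD7 (0.65) and LEF1 (0.43) rose and AXIN2 fell (−0.51) among WNT-beta-catenin targets (8 higher, 6 lower of 18, median 0.11). Apoptosis regulators had 9 higher and 4 lower of 24 (median 0.15), with XIAP (0.87) and BMF (0.54) higher and PMAIP1 lower (−0.55). SC5D (1.66) and INSIG1 (0.63) rose and FADS2 (−1.52) and ACLY (−1.01) fell among cholesterol and fatty acid synthesis genes (10 higher, 8 lower of 30, median 0.09). The counts higher and lower were 8 and 6 of 26 p53 targets (median −0.02), 6 and 2 of 16 NF-kB and inflammatory cytokine genes (0.06), 3 and 11 of 31 glycolysis and hypoxia genes (−0.12), and 6 and 3 of 15 small RNA pathway genes (0.07). They were 7 and 1 of 13 mitochondrially encoded genes (0.25) and 6 and 1 of 59 cytosolic ribosomal protein genes (0.08). Of markers of other cell types, 2 of 9 fibroblast genes (THY1, 2.70, and POSTN, 2.72), 1 of 4 leukocyte genes (CD68, 0.44) and 0 of 4 keratinocyte genes rose, and 1 of 2 endothelial genes fell (VWF, −1.46), a call lost without 13.6 replicate 2 (−1.39) or 3 (−1.30). FADS2, AXIN2, BMF, NDUFB10 and HYOU1 hold GCTCTGT in their 3′ UTRs, and ETV5, SC5D and TBX2 hold GATTAAC.

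In all, 7357 genes changed with 13.6 (49.9% of the 14731 tested), 3668 higher and 3689 lower, of which 586 and 607 changed at least 2-fold. The counts of list members that changed are to be read beside that share. The median size of the called changes was 0.50 on the log2 scale. Of 26 lists tested by camera with a preset correlation 9 passed, 3 up and 6 down, and 0 passed with an estimated correlation (4 at an unadjusted p under 0.05). By fry, whose p tests whether a list's genes move on balance 1 way without comparing them with other genes, 17 lists passed. Adjusted over the list alone, the counts higher and lower were 4 and 15 for melanin genes, 7 and 12 for cAMP-CREB genes, 16 and 4 for adhesion genes, 9 and 6 for p53 targets, 3 and 25 for G2 and M-phase genes, 4 and 15 for the integrated stress response, 1 and 12 for NRF2 targets, 11 and 9 for cholesterol genes, 3 and 10 for glycolysis genes, 4 and 1 for ribosomal protein genes and 10 and 4 for apoptosis regulators. Adjusted over the list alone, the other lists kept the counts given. The median, mean and test differed in sign for the reported TBX3 targets (median 0.32, mean −0.13, test up), the T-box family (median 0.08, mean 0.19, test down), p53 targets (median −0.02, mean −0.04, test up) and fibroblast markers (median −0.14, mean 0.29, test up).

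**Figure D2:**
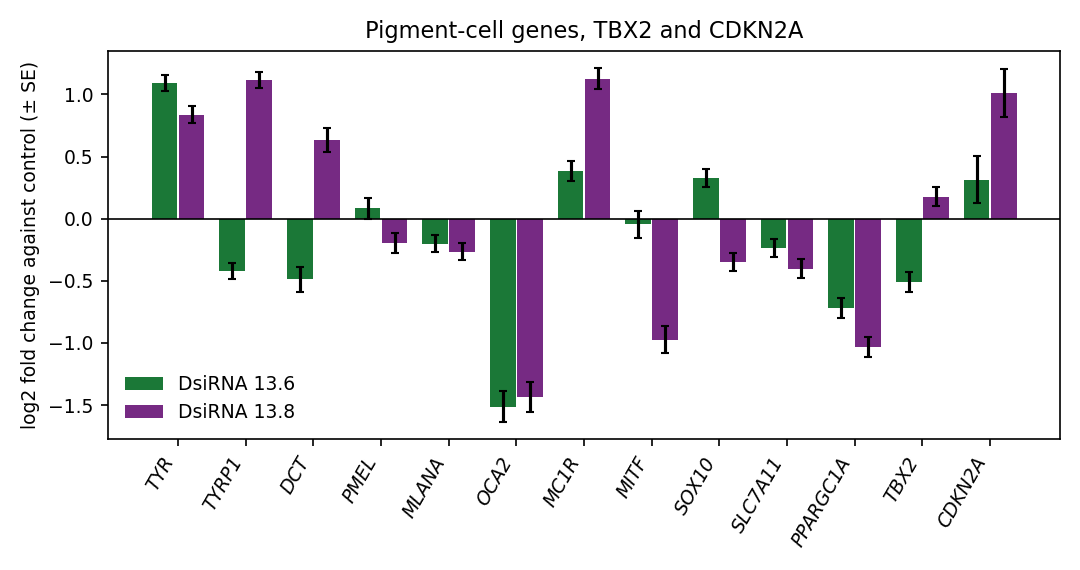
Log2 fold changes against the control DsiRNA, with SE, for the pigment-cell genes fixed in advance and for TBX2 and CDKN2A, with DsiRNA 13.6 in green and 13.8 in purple. TYRP1 (−0.42 and 1.12) and DCT (−0.49 and 0.64) moved in opposite directions, while TYR (1.09 and 0.84) and OCA2 (−1.51 and −1.44) moved the same way.

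DsiRNA 13.8 against control asks the same question with the second reagent, which left 41.4% of the control's TBX3 mRNA. The chemokine CCL2, which draws monocytes, rose from 39 reads in the 3 controls to 2590 reads (56.0-fold after scaling by library totals, 95% exact interval 40.8 to 78.9 for counting error only, fitted log2 fold change 5.78 ± 0.25). The interferon-induced genes IFI44 (4.55 ± 0.22) and IFIT1 (3.601 ± 0.142) rose, as did ANXA1, an annexin that binds membranes with calcium (11.0 ± 4.0 to 178 ± 33.8 CPM, 4.01 ± 0.23). PRELP, a matrix proteoglycan (3.87 ± 0.13), and the collagen receptor kinase DDR2 (3.28 ± 0.20) completed the 6 largest rises among genes with a mean of at least 5 CPM. Under the same floor the largest falls were those of the mitotic kinase PLK1 (162 ± 7.5 to 26.3 ± 1.9 CPM, −2.63 ± 0.07), APOLD1 (−2.58 ± 0.12), the nuclear receptor NR4A3 (−2.48 ± 0.08) and MAPK4, an atypical MAP kinase (−2.41 ± 0.08). ESR2, which encodes estrogen receptor beta (−2.27 ± 0.17), and PIGA, an enzyme of GPI-anchor synthesis (−2.18 ± 0.07), followed. All 3 knockdown libraries lay beyond all 3 controls in these 12 genes by the rule that chose them, so this is not a result. The 3′ UTRs of PLK1, APOLD1 and PIGA hold the 7-base word AACTGTC, the word with the lowest t statistic with 13.8 in the search. In the held-out genes its carriers were 0.226 lower than others (permutation p = 0.0001, the smallest possible), against 0.046 higher with 13.6 (permutation p = 0.0576).

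Among pigment-cell genes, TYRP1 rose with 13.8 from 3604 ± 142 to 7831 ± 147 CPM (1.12 ± 0.06), TYR by 0.84 ± 0.07 and DCT by 0.64 ± 0.10, while OCA2 fell by 1.44 ± 0.12 and MLANA by 0.27 ± 0.07. MITF fell from 792 ± 115 to 403 ± 55.6 CPM (−0.97 ± 0.11) and SOX10 by 0.35 ± 0.07, while MC1R rose from 24.3 ± 2.6 to 52.9 ± 3.5 CPM (1.13 ± 0.08) and PMEL stood at −0.20 ± 0.08. RAB38 (−1.85) and the AP-3 adaptor subunits AP3D1 (−1.39) and AP3B1 (−1.26), which sort melanosome cargo, fell, and all 3 hold AACTGTC in their 3′ UTRs. Of the 30 melanin and melanosome genes 7 rose, 11 fell and 12 did not pass the test (median −0.18, camera adjusted p = 0.18). Of 33 MITF programme genes 7 rose, 12 fell and 14 did not pass (median −0.17, camera adjusted p = 0.274), with falls of the kinase CDK2 (−1.09) and of RAB27A, which tethers melanosomes (−0.92). The pheomelanin and cysteine-glutathione list had 5 of 22 genes higher and 10 lower (median −0.13, camera adjusted p = 0.266). GCLC rose by 1.19, while the lysosomal cystine exporter CTNS (−0.83), CTH (−0.63), MGRN1 (−0.56) and SLC7A11 (−0.40 ± 0.07) fell.

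MC1R and cAMP-CREB signalling genes fell with 13.8, with 17 of 27 lower, 3 higher and 7 not past the test (median −0.48, camera adjusted p = 3.5e-04, and adjusted p = 0.196 with an estimated correlation). NR4A3, its relative NR4A1 (−1.41), the protein kinase A subunit PRKACB (−1.47), PPARGC1A (−1.03 ± 0.08) and the phosphodiesterase PDE3A (−0.84) fell, against the rise of MC1R itself. PRKACB, NR4A1 and PDE3A hold AACTGTC, as do MGRN1 and SLC7A11 of the pheomelanin list. MAPK-ERK output genes were lower in 11 and higher in 3 of 21 (median −0.31, camera adjusted p = 0.104), with falls of SPRY1 (−1.73), which holds AACTGTC, and of the immediate-early genes EGR1 (−1.14) and FOS (−0.69), and a rise of ETV1 (1.72).

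Proliferation genes fell further with 13.8. All but 2 of the 35 G2 and M-phase genes fell, 33 in number, with HMMR higher (0.24) and 1 not past the test (median −1.26, camera adjusted p = 7.5e-17, and adjusted p = 0.105 with an estimated correlation). PLK1, cyclin B1 (CCNB1, −1.96), the kinesin KIF2C (−1.65) and the centromere chaperone HJURP (−1.55) were among those that fell. Of 35 S-phase genes 32 fell, 0 rose and 3 did not pass the test (median −0.96, camera adjusted p = 3.4e-14, and adjusted p = 0.105 with an estimated correlation). The flap endonuclease FEN1 (−1.33), the licensing factor CDC6 (−1.07), CHAF1B (−1.58) and the checkpoint mediator CLSPN (−1.67) were among them. CDKN2A, which encodes the inhibitor p16, rose from 177 ± 51.9 to 355 ± 73.2 CPM (1.01 ± 0.19), NCAM1 rose by 0.58, and CDKN1A fell to 1, 3 and 2 reads (0.0803 of control after scaling by library totals, 95% exact interval 0.0284 to 0.185 for counting error only, fitted −3.53 ± 0.63). CDH1 stood at 0.23 ± 0.20 and the list of 5 reported TBX3 targets did not pass (camera adjusted p = 0.274).

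Interferon-stimulated genes rose, with 25 of 33 measured genes higher, 4 lower and 4 not past the test (median 1.06, camera adjusted p = 3.9e-07, and adjusted p = 0.105 with an estimated correlation). IFIT1, IFI44, IFIT3 (2.36) and DDX60 (2.05) were among them. Epithelial-mesenchymal and adhesion genes rose, with 13 of 24 measured genes higher, 2 lower and 9 not past the test (median 0.45, camera adjusted p = 0.00598, and adjusted p = 0.549 with an estimated correlation). Integrins ITGAV (1.15) and ITGB1 (0.86), the matrix protease MMP14 (0.86) and vimentin (VIM, 0.74) rose. Of 21 genes of the undifferentiated and neural crest-like state 9 rose, 2 fell and 10 did not pass the test (median 0.45, camera adjusted p = 0.057), with rises of ITGA5 (2.02), WNT5A (1.54) and CTGF (0.80). Beside these mesenchymal genes all 9 measured fibroblast markers rose (median 1.86, camera adjusted p = 5.97e-04, and adjusted p = 0.105 with an estimated correlation). Their levels were low: LUM went from 3.1 to 10.9 CPM (1.81), THY1 from 0.4 to 3.7 CPM (3.26) and FAP from 0.3 to 3.3 CPM (3.64), and POSTN from 9 to 608 reads over 3 libraries. Of the other cell-type markers, 1 of 4 keratinocyte genes fell (DSP, −1.05), 1 of 4 leukocyte genes rose (LYZ, 0.83) and 1 fell (ITGAM, −1.27), and neither of 2 endothelial genes passed the test. The LYZ call was lost without control replicate 1 (0.62) or 13.8 replicate 3 (0.73). The ITGAM call was lost without control replicate 1 (−1.29), 2 (−1.27) or 3 (−1.25) or 13.8 replicate 2 (−0.996) or 3 (−1.36). The ITGAM call was also lost with the replicate block (−1.27), with DESeq2 (−1.29) and with no filter on low counts (−1.28).

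Unfolded protein response genes rose, with 13 of 21 higher, 2 lower and 6 not past the test (median 0.31, camera adjusted p = 0.00717, and adjusted p = 0.105 with an estimated correlation). CRELD2 (0.88), PDIA4 (0.74) and HSP90B1 (0.65) rose and PDIA6, which holds AACTGTC, fell by 1.05. Cytosolic ribosomal protein genes rose, with 24 of 59 higher, 0 lower and 35 not past the test (median 0.25, camera adjusted p = 3.5e-04, and adjusted p = 0.732 with an estimated correlation), among them RPL7A (1.16), RPL4 (0.49), RPL7 (0.47) and RPL6 (0.43). Mitochondrially encoded genes rose, with 7 of 13 higher, 1 lower and 5 not past the test (median 0.26, camera adjusted p = 0.0413, and adjusted p = 0.72 with an estimated correlation), among them ND2 (0.52), ATP8 (0.41), ND3 (0.40) and ND1 (0.37). Mitochondrial transcripts took 3.67 ± 0.13% of reads with 13.8, 3.39 ± 0.18% with 13.6 and 3.15 ± 0.31% in the controls. The mitochondrial list did not pass without control replicate 1 (camera adjusted p = 0.0715) or 3 (0.0704), 13.6 replicate 1 (0.0527), or 13.8 replicate 1 (0.0699) or 2 (0.0508).

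Other lists did not pass with 13.8. Small RNA pathway genes were lower in 8 and higher in 2 of 15 (median −0.21, camera adjusted p = 0.0922), with falls of DROSHA (−0.76), DGCR8 (−0.68), PRKRA (−0.67) and AGO2 (−0.54). Glycolysis and hypoxia genes were lower in 16 and higher in 5 of 31 (median −0.33), where ANKRD37 (−1.24) and ADM (−0.84) fell and PGAM1 rose (1.65). The integrated stress response list had 12 of 29 lower and 5 higher (median −0.12), where ATF3 fell (−1.11) and PSAT1 rose (2.39 ± 0.06). Among p53 targets 10 of 26 were lower and 5 higher (median −0.04), with RRM2B (−1.16) and AEN (−0.92) lower and ZMAT3 (1.40) higher. Apoptosis regulators were higher in 8 and lower in 6 of 24 (median 0.12), with rises of BIK (2.81) and XIAP (0.54) and a fall of MCL1 (−0.82). NF-kB and inflammatory cytokine genes were higher in 3 and lower in 4 of 16 (median −0.01): CCL2 and CXCL8 (2.36 ± 0.20) rose, and NFKBIZ (−1.21) and TNFAIP3 (−0.82), which act downstream of NF-kB, fell. The counts higher and lower were 7 and 5 of 17 NRF2 targets (median 0.07), 7 and 10 of 30 cholesterol and fatty acid synthesis genes (−0.16), 16 and 6 of 47 oxidative phosphorylation genes (0.16), 6 and 5 of 18 WNT-beta-catenin targets (−0.06) and 1 and 2 of 8 T-box genes (0.12), of which TBX15 rose (1.59) and TBX2 stood at 0.18 ± 0.08. DGCR8 and ADM hold AACTGTC, and AGO2 and ZMAT3 hold both GATTAAC and GCTCTGT. AACTGTC also lies in genes that rose with 13.8, among them RPL4, the fibroblast marker DCN and the adhesion gene ALCAM.

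In all, 8169 genes changed with 13.8 (55.5% of the 14731 tested), 4053 higher and 4116 lower, of which 1103 and 585 changed at least 2-fold. The counts of list members that changed are to be read beside that share. Of 26 lists 9 passed by camera with a preset correlation, 6 up and 3 down, 0 passed with an estimated correlation (6 at an unadjusted p under 0.05), and 17 passed by fry. Adjusted over the list alone, the counts higher and lower were 3 and 18 for cAMP-CREB genes, 25 and 5 for interferon-stimulated genes, 6 and 12 for the integrated stress response, 15 and 2 for the unfolded protein response, 5 and 17 for glycolysis genes, 15 and 5 for oxidative phosphorylation, 8 and 1 for mitochondrially encoded genes and 20 and 0 for ribosomal protein genes, and as given for the other lists. Median, mean and test differed in sign for the reported TBX3 targets (0.49, −0.25 and up), the T-box family (0.12, 0.08 and down), WNT-beta-catenin targets (−0.06, 0.08 and down) and NF-kB genes (−0.01, 0.38 and down).

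**Figure D3:**
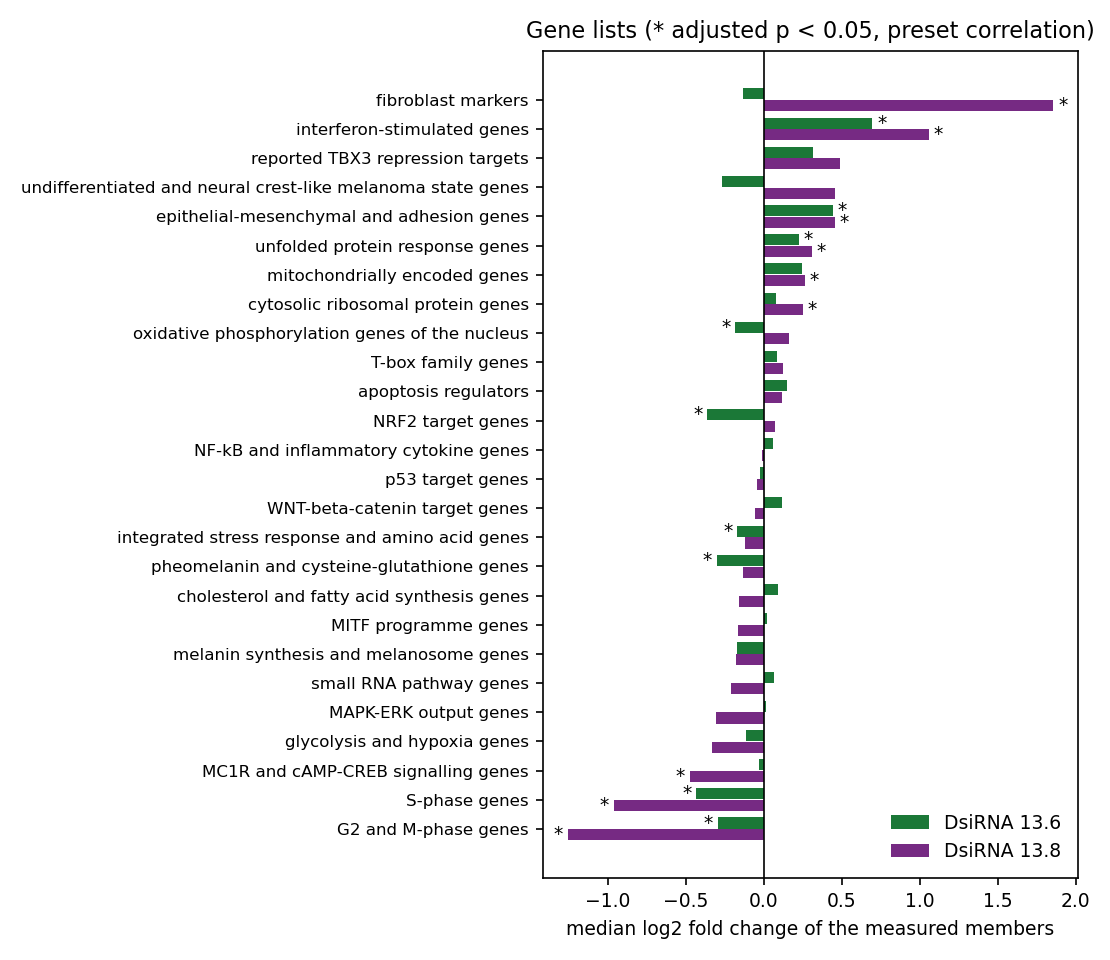
Median log2 fold change of the measured members of each of 26 gene lists with DsiRNA 13.6 (green) and 13.8 (purple) against control, with a star where camera with a preset correlation gave an adjusted p under 0.05. G2 and M-phase genes (−0.30 and −1.26) and S-phase genes (−0.43 and −0.96) lie lowest with 13.8, and interferon-stimulated genes (0.69 and 1.06) lie high with both.

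Genes that moved the same way with both DsiRNAs are those that 2 reagents against 1 target share. SESN3 rose by 3.03 and 2.92 with 13.6 and 13.8, the dehydrogenase GPD1L by 2.78 and 2.46, OAS1 by 2.88 and 2.41, and COL9A1, a collagen chain, by 2.32 and 2.51. PSAT1 rose by 2.29 and 2.39, TNFSF13B by 2.94 and 2.29, ID3, an inhibitor of helix-loop-helix transcription factors, by 2.24 and 2.37, and ALCAM, an adhesion molecule, by 2.05 and 2.41. IFI44 rose by 2.19 and 4.55 and the sorting nexin SNX22 by 2.05 ± 0.46 and 2.89 ± 0.45. MS4A15 fell by 2.70 and 1.82, UBAP1L by 2.69 and 1.68, the peptidase DESI2 by 1.76 and 1.93, the muscle coregulator PERM1 by 1.72 and 1.63, and MAPK4 by 1.63 and 2.41. OCA2 fell by 1.51 and 1.44, the exchange factor ARHGEF39 by 1.40 and 1.58, FAM178B by 1.34 and 1.70, the ubiquitin ligase adaptor DCAF12 by 1.28 and 1.53, and RPRD1B, which binds RNA polymerase II, by 1.31 and 1.26. All 6 knockdown libraries lay beyond all 3 controls in these 20 genes by the rule that chose them, so this is not a result. GPD1L, TNFSF13B and ALCAM hold GATTAAC in their 3′ UTRs, as do 13.9% of the 1565 searched genes higher with both and 5.89% of all 12374 searched. ALCAM also holds AACTGTC, though it rose with 13.8. Held-out genes with GATTAAC were 0.292 higher than others with 13.6 and 0.254 higher with 13.8 (permutation p = 0.0001 for each, the smallest possible). DESI2, DCAF12 and RPRD1B hold both GCTCTGT and AACTGTC.

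Taking the mean of both DsiRNAs against control, 7398 genes changed (50.2% of the 14731 tested), 3437 higher and 3961 lower. Of 26 lists 12 passed by camera with a preset correlation, 0 with an estimated correlation (6 at an unadjusted p under 0.05) and 15 by fry. Interferon-stimulated genes were higher in 26 and lower in 3 of 33 (camera adjusted p = 1.3e-08, and adjusted p = 0.143 with an estimated correlation), and adhesion genes higher in 17 and lower in 1 of 24 (camera adjusted p = 3.6e-05, and adjusted p = 0.265 with an estimated correlation). Lower were G2 and M-phase genes in 33 of 35 (camera adjusted p = 4.3e-13) and S-phase genes in 31 of 35 (camera adjusted p = 2.4e-12), each with adjusted p = 0.143 with an estimated correlation. Fibroblast markers were higher in 5 of 9 (camera adjusted p = 0.0115) and unfolded protein response genes in 14 of 21 (camera adjusted p = 0.0105), each with adjusted p = 0.143 with an estimated correlation. cAMP-CREB genes were lower in 15 of 27 (camera adjusted p = 0.0056, and adjusted p = 0.294 with an estimated correlation) and the pheomelanin list in 12 of 22 (camera adjusted p = 0.0242, and adjusted p = 0.143 with an estimated correlation). The melanin list was lower in 15 of 30 and higher in 6 (camera adjusted p = 0.0409, and adjusted p = 0.629 with an estimated correlation), and the integrated stress response lower in 14 of 29 (camera adjusted p = 0.0242, and adjusted p = 0.593 with an estimated correlation). Mitochondrially encoded genes were higher in 7 of 13 (camera adjusted p = 0.0242, and adjusted p = 0.675 with an estimated correlation). Ribosomal protein genes were higher in 15 of 59 (camera adjusted p = 0.00185, and adjusted p = 0.862 with an estimated correlation). Adjusted over the list alone, the melanin list had 6 higher and 17 lower, the pheomelanin list 2 and 13, interferon-stimulated genes 26 and 4, the integrated stress response 3 and 16, mitochondrially encoded genes 8 and 0 and ribosomal protein genes 6 and 0, and the other 6 of these lists kept their counts. Median, mean and test differed in sign for the reported TBX3 targets (0.31, −0.19 and up), the T-box family (−0.01, 0.13 and down) and MAPK-ERK output genes (−0.01, 0.01 and down). By camera, the adjusted p without 1 control library was 0.0698 (replicate 2) or 0.0636 (replicate 3) for melanin genes, 0.0681 (replicate 3) for the pheomelanin list, 0.0636 (replicate 3) for the integrated stress response, 0.0523 (replicate 1) or 0.0896 (replicate 3) for mitochondrially encoded genes and 0.0523 (replicate 1) for ribosomal protein genes. With genes holding any of the 3 words left out it was 0.444 for melanin genes, and with genes of a mean of at least 50 reads alone it was 0.0658 for melanin genes and 0.0606 for the integrated stress response.

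Of the 4627 genes called with both DsiRNAs, 3300 moved the same way, 1714 higher and 1586 lower, and 1327 (28.7%) moved in opposite directions. A further 2730 genes were called with 13.6 alone and 3542 with 13.8 alone. Independent lists of these sizes would share 1009 higher and 1031 lower genes and hold 2040 opposite pairs. In 20 simulations of unchanged groups against the shared controls edgeR called 0 genes with both DsiRNAs and at most 2 with either. Across genes, which are not independent replicates, the log2 fold changes had Pearson's r = 0.329 and Spearman's rho = 0.297, against a mean r of 0.506 in the simulations, where chance values of the controls are all there is to share. The covariance was 0.150 against a simulated mean of 0.0229 (0.0202 to 0.0242), a difference of 0.127. The 3 controls are too few to give each DsiRNA at least 2 of its own, so part of the excess may come from the shared controls. The simulations drew genes independently and hold no shifts of the controls that many genes share.

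**Figure D4:**
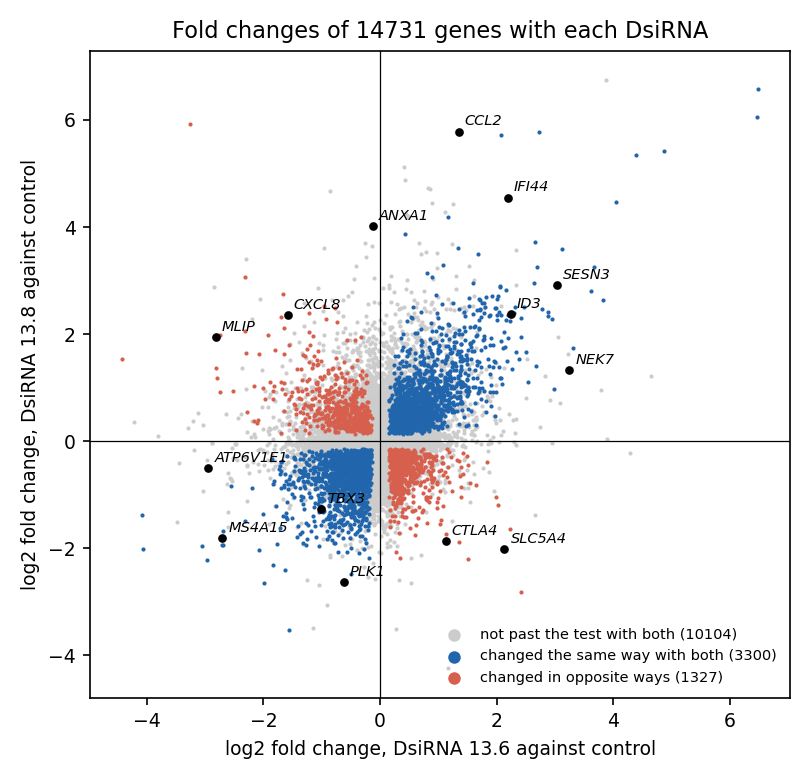
Log2 fold change with DsiRNA 13.8 against that with DsiRNA 13.6 for 14731 genes, each point a gene, coloured by whether both changes passed the test in the same direction (3300, blue), in opposite directions (1327, red) or not both (grey). SESN3 and ID3 lie high with both, and MLIP, CXCL8, CTLA4 and SLC5A4 lie in the opposite quadrants.

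DsiRNA 13.6 against DsiRNA 13.8 asks where 2 reagents against 1 target part. The glucose sensor SLC5A4 was 4.15 ± 0.30 higher on the log2 scale with 13.6 (31.3 ± 4.0 against 1.8 ± 0.4 CPM, control 7.2 ± 3.6), having risen with 13.6 (2.13) and fallen with 13.8 (−2.02). The salivary peptide gene HTN1 differed by 3.21 ± 0.16, the T-cell checkpoint receptor CTLA4 by 2.99 ± 0.09, ACSL5 by 2.97 ± 0.11 and the kinase NUAK1 by 2.87 ± 0.15. Lower with 13.6 were MLIP (−4.76 ± 0.19, 0.5 ± 0.2 against 14.2 ± 1.0 CPM, control 3.7 ± 0.4), CCL2 (−4.44 ± 0.21), ANXA1 (−4.13 ± 0.23), the neutrophil chemokine CXCL8 (−3.94 ± 0.22) and INHBE, an activin subunit (−3.76 ± 0.15). MLIP (−2.82 and 1.95), CXCL8 (−1.59 and 2.36) and INHBE (−1.64 and 2.12) each fell with 13.6 and rose with 13.8, and HTN1 (2.02 and −1.19), CTLA4 (1.12 and −1.87), NUAK1 (1.14 and −1.74) and PIGA (0.35 and −2.18) did the reverse. NUAK1 and INHBE hold GCTCTGT, and PIGA holds both GCTCTGT and AACTGTC.

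Of the pigment genes, TYRP1 (−1.54 ± 0.07), DCT (−1.12 ± 0.10) and MC1R (−0.74 ± 0.08) were lower with 13.6, while MITF was 0.93 ± 0.11, SOX10 0.67 ± 0.07 and TYR 0.25 ± 0.06 higher. TBX2 (−0.69 ± 0.08) and CDKN2A (−0.69 ± 0.19) were lower with 13.6, and PPARGC1A was higher (0.31 ± 0.08). The CDKN2A call was lost with no filter on low counts (−0.67) and with GC content and length corrected (−0.34). OCA2, MLANA and SLC7A11 did not differ past the threshold (−0.07 ± 0.12, 0.07 ± 0.07 and 0.17 ± 0.07). PMEL was 0.28 ± 0.08 higher with 13.6, a call lost without 13.6 replicate 3 (0.24), and CDKN1A 1.97 ± 0.74 higher, a call lost without 13.6 replicate 3 (1.59) or 13.8 replicate 1 (1.70) or 3 (1.99). ASIP and HGF, ligands of pigment-cell receptors, lay at 1.8 CPM or below in every group and changed in no comparison.

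All 35 G2 and M-phase genes were higher with 13.6 than with 13.8 (median 0.92, camera adjusted p = 1.9e-14, and adjusted p = 0.331 with an estimated correlation), among them PLK1 (2.01), CCNB1 (1.80), TTK (1.26) and DLGAP5 (1.14). Of 35 S-phase genes 28 were higher, 2 lower and 5 not past the test (median 0.53, camera adjusted p = 8.0e-07, and adjusted p = 0.418 with an estimated correlation). cAMP-CREB genes were higher in 17, lower in 5 and not past the test in 5 of 27 (median 0.31, camera adjusted p = 0.00877, and adjusted p = 0.527 with an estimated correlation), with NR4A3 (1.99), NR4A1 (1.52), PRKACB (1.07) and CREM (0.88) higher. With genes holding any of the 3 words left out that list gave adjusted p = 0.158 by camera. Small RNA pathway genes were higher in 11, lower in 2 and not past the test in 2 of 15 (median 0.31, camera adjusted p = 0.0244, and adjusted p = 0.637 with an estimated correlation), among them PRKRA (0.95), ADAR (0.82), DICER1 (0.62) and AGO3 (0.59). With the word-holding genes left out they gave adjusted p = 0.47 by camera. ADAR, CREM and AGO3 hold AACTGTC, as does DICER1, and AGO3 and DICER1 also hold GCTCTGT.

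Lower with 13.6 than with 13.8 were NRF2 targets (12 of 17 lower, 0 higher, 5 not past the test, median −0.51, camera adjusted p = 0.00526, and adjusted p = 0.331 with an estimated correlation), among them FTH1, a ferritin subunit (−0.95), OSGIN1 (−0.97) and SRXN1 (−0.79). Oxidative phosphorylation genes were lower in 27, higher in 6 and not past the test in 14 of 47 (median −0.33, camera adjusted p = 0.00526, and adjusted p = 0.825 with an estimated correlation), among them NDUFB10 (−1.57), which holds GCTCTGT, and the complex III subunit UQCRC2 (−0.67). Fibroblast markers were lower in 8 of 9 (median −2.06, camera adjusted p = 0.00382, and adjusted p = 0.277 with an estimated correlation), beside lower undifferentiated-state genes in 11, higher in 3 and not past the test in 7 of 21 (median −0.83, camera adjusted p = 0.022, and adjusted p = 0.535 with an estimated correlation). Of these, LOXL2 (−2.86), CYR61 (−2.29) and CTGF (−2.19) were lower and CCND1 (0.81), which holds AACTGTC, was higher. The undifferentiated list did not pass without 13.6 replicate 2 (camera adjusted p = 0.0529) or 13.8 replicate 2 (camera adjusted p = 0.0537). Ribosomal protein genes were lower in 20 and not past the test in 39 of 59 (median −0.21, camera adjusted p = 0.022, and adjusted p = 0.896 with an estimated correlation), and this list did not pass without 13.6 replicate 1 (camera adjusted p = 0.17) or 13.8 replicate 2 (0.106) or 3 (0.0742), or with the word-holding genes left out (0.0563).

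Not past the test between the DsiRNAs were interferon-stimulated genes (5 higher, 15 lower of 33, camera adjusted p = 0.062), though IFIT1 (−2.26), IFI44 (−2.36) and BST2 (−3.04) were lower with 13.6, and MAPK-ERK output genes (13 higher, 5 lower of 21, camera adjusted p = 0.062), though EPHA4 (1.74) and SPRY1 (1.64) were higher. Melanin genes split 9 higher and 9 lower of 30, MITF programme genes 16 and 7 of 33, and adhesion genes 9 and 8 of 24. In all, 8995 genes differed (61.1% of the 14731 tested), 4547 higher and 4448 lower with 13.6, of which 731 and 1332 differed at least 2-fold. Of 26 lists 9 passed by camera with a preset correlation, 0 with an estimated correlation (3 at an unadjusted p under 0.05) and 17 by fry. Adjusted over the list alone, the counts higher and lower were 3 and 12 for undifferentiated-state genes, 0 and 3 for ribosomal protein genes, 0 and 9 for fibroblast markers, 13 and 6 for MAPK-ERK genes and 9 and 9 for adhesion genes, and as given for the other lists named in this comparison. Median, mean and test differed in sign for adhesion genes (−0.05, 0.02 and down), the reported TBX3 targets (−0.18, 0.12 and down), p53 targets (−0.01, 0.14 and up), NF-kB genes (0.27, −0.12 and up), mitochondrially encoded genes (0.0042, −0.07 and down) and apoptosis regulators (0.06, −0.03 and up). Ribosomal protein genes and other genes with near-identical copies, and genes that overlap on opposite strands, are uncertain, since the counting's treatment of shared and antisense reads is not given in the sources used here.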

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

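The tests of the words, of knockdown depth, of GC content and length, and of the splits in this part were chosen only after the results were seen. The prediction for the shared controls was also written then. The test of the difference between the DsiRNAs was planned. The results given here were singled out because the effects of the 2 DsiRNAs against the same controls differ by the test of DsiRNA 13.6 against 13.8. With 3 libraries in each group no library was tested as far from the others, and no signal was looked for outside the count table.

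By edgeR's test 8995 genes differ between the DsiRNAs, and 1327 genes were called in opposite directions against the controls, all of them also past the test of the difference. Of the genes reported, 34 went in opposite directions. Those named for the size of their change or fixed in advance had differences of log2 fold changes (13.6 minus 13.8) of −4.76 for MLIP, −3.94 for CXCL8, −3.76 for INHBE, −1.54 for TYRP1, −1.12 for DCT, 0.67 for SOX10, 2.53 for PIGA, 2.87 for NUAK1, 2.99 for CTLA4, 3.21 for HTN1 and 4.15 for SLC5A4. Among the list members reported the differences were −2.55 for MFSD12, −2.19 for CTGF, −1.22 for CHAC1, −1.17 for ASNS, −0.97 for OSGIN1, −0.95 for FTH1, −0.79 for SRXN1 and −0.67 for UQCRC2. They were 0.77 for ATF6, 0.81 for CCND1, 0.82 for ADAR, 0.83 for DUSP4, 0.88 for CREM, 0.93 for INSIG1, 0.95 for PRKRA, 1.01 for LEF1, 1.02 for FASN, 1.05 for ETV5, 1.23 for SNAI2, 1.49 for ST3GAL6, 1.52 for RRM2B, 1.74 for EPHA4 and 1.86 for PDIA6. The lists that differ by camera had median differences of 0.31 for MC1R and cAMP-CREB signalling, −0.83 for the undifferentiated and neural crest-like state, 0.53 for S phase, 0.92 for G2 and M phase, −0.51 for NRF2 targets, −0.33 for oxidative phosphorylation, −0.21 for ribosomal proteins, 0.31 for the small RNA pathway and −2.06 for fibroblast markers. None of these 9 lists passed with an estimated correlation, where adjusted p ran from 0.277 for fibroblast markers to 0.896 for ribosomal proteins. The call for the undifferentiated state was lost without 13.6 replicate 2 (camera adjusted p = 0.0529) or 13.8 replicate 2 (0.0537), and that for ribosomal proteins without 13.6 replicate 1 (0.17) or 13.8 replicate 2 (0.106) or 3 (0.0742). With genes holding any of the 3 words left out, camera gave adjusted p = 0.0563 for ribosomal proteins, 0.158 for cAMP-CREB signalling and 0.47 for the small RNA pathway.

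The first pattern weighed is that the responses to the 2 DsiRNAs differ. A deeper knockdown with 13.8 was argued against as the whole cause, since 1327 genes were called in opposite directions. That holds only if each gene keeps its direction as TBX3 falls, which was not tested. Knockdown depth was measured as TBX3 mRNA only. A GC content or length bias cannot be the whole cause, since 9456 genes differed after that correction. Silencing through short matches in 3′ UTRs may account for part. Held-out genes with GCTCTGT lay at −0.147 against the others with 13.6 and those with AACTGTC at −0.226 with 13.8. The held-out genes come from the same 9 libraries and are no new experiment. Each word also lies in the TBX3 transcript, as do 22.4% of all words. Of the genes that differ 69.4% carry neither word, against 71.8% of all searched genes. That share had to be large whatever the cause, since 2592 and 1379 searched genes hold the words and 7897 differ. The match of either word to a DsiRNA is a hypothesis, since the reagent sequences are not given in the sources used here. Effects of each DsiRNA on other transcripts without these words, and what follows from them in the cells, stay open and untested.

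The second pattern is the set of 1714 genes higher with both DsiRNAs. Genes with GATTAAC, a word absent from the TBX3 transcript, were 0.274 higher in the held-out genes, so a candidate explanation for some of them is a word silenced by the control DsiRNA and released in both knockdown groups. The word cannot act directly on all of these genes, since 86.1% of the searched genes higher with both lack it, against 94.1% of all searched genes. That most lack it was fixed in advance, as 729 searched genes hold the word and 1565 were higher with both. Effects of the control DsiRNA on transcripts without this word, and what follows from its release in the cells, stay open and untested. Chance values of the shared controls that arise gene by gene were argued against as the whole cause. The covariance of the changes lay 0.127 above that of unchanged groups, though part of the excess may come from the controls. The simulations drew genes independently, so they cannot exclude shifts of the controls that many genes share. A response to the loss of TBX3, the design's own explanation, stays open and was not tested apart from these.

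The third pattern is that S-phase and G2 and M-phase genes were lower, and more so with 13.8. The word AACTGTC cannot be the whole cause through these genes themselves, since the 34 of 35 S-phase genes and 34 of 35 G2 and M-phase genes that lack it had medians of −0.97 (95% interval −1.11 to −0.77) and −1.25 (−1.30 to −1.10). These intervals come from resampling the genes, which move together, and leave out the spread between libraries. A fall in proportion to TBX3 was argued against, since the median with 13.8 was 2.22 times that with 13.6 for S phase (1.99 to 3.22 over all 27 choices of 1 library per group) and 4.22 times for G2 and M phase (3.16 to 8.06), while the TBX3 ratio was 1.25 (1.10 to 1.54). A response to TBX3 loss that is steeper than proportional, and an indirect effect of PLK1, which holds AACTGTC, stay open and were not tested. The list calls rest on a preset correlation, and with an estimated correlation camera gave adjusted p = 0.105 for each list with 13.8, and 0.418 for S phase and 0.331 for G2 and M phase between the DsiRNAs.

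For other splits of the libraries, those within a pair of groups number 10, too few for a share under 0.05. The real and the highest other count of genes in fits of the compared libraries were 6998 and 0 for 13.6 against control (1 of 10 splits as large), 7609 and 0 for 13.8 against control (1 of 10) and 9581 and 0 for 13.6 against 13.8 (1 of 10). The counts of lists were 8 and 9 (2 of 10), 10 and 11 (3 of 10) and 10 and 11 (2 of 10). For both DsiRNAs against control, in a fit of 2 groups that is not the one behind the 7398 genes, the real split gave 2510 genes and 3 of 84 splits gave as many, and it gave 13 lists, with 1 of 84 as large and 11 the highest other. The splits with more genes set the 13.8 libraries (5522) or the 13.6 libraries (4036) against the rest, and every split that mixed the groups gave 0. The splits therefore exclude chance only for a difference among the 3 groups, and do not show that the controls stand apart from both DsiRNAs.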

How the results depend on the processing

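The fits without genes that hold the 3 words, and with GC content and length corrected, were chosen only after the results were seen; the other alternatives were planned. Counts of genes are given in the order 13.6 against control, 13.8 against control, mean of both, 13.6 against 13.8, changed the same way by both, and opposite ways. Against a 1.2-fold change glmTreat gave 4124, 5071, 3662, 5938, 1496 and 373, and a fold of at least 2 gave 1193, 1688, 867, 2063, 310 and 63, both fewer by construction. An adjusted p under 0.01 left 728 opposite calls, and leaving out genes with the 3 words left 817 among 10857 tested. With control and all 6 knockdown libraries as 2 groups the mean of both gave 2510, as differences between the DsiRNAs then count as spread. Every other alternative for these counts stayed within 1.5 times: DESeq2 gave 7563, 8330, 7594 and 9113, limma-voom 7306, 8251, 7335 and 9049, and the GC and length correction 7969, 8926, 8155, 9456, 3865 and 1601. Each library left out in turn gave 6304 to 7504, 7164 to 8452, 6623 to 7490, 8021 to 9603, 2881 to 3497 and 1060 to 1350, and TBX3 log2 fold changes of −1.09 to −0.97 and −1.30 to −1.24. The correlations do not settle whether the replicate numbers pair the libraries: same-number pairs had −0.179 to 0.187, other pairs −0.248 to 0.187. The replicate block gave 8010, 8803, 8033, 9581, 3705 and 1600 genes and 9, 9, 12 and 11 lists. Each of these gene counts was above that of the main fit, so an effect shared by replicate number cannot be excluded. Lists past camera numbered 9, 9, 12 and 9, and 0 in each comparison with an estimated correlation, which allows for members that move together. Fry, which makes no comparison with other genes, gave 17, 17, 15 and 17, and leaving out each library 7 to 10, 8 to 11, 8 to 13 and 7 to 10. Of 9567 values of named genes under the alternatives 9493 kept their side of the threshold, 47 lost and 27 gained a call, and 0 called genes reversed. Among the 9493 were 33 uncalled values whose sign flipped. For lists, 1626 values kept their side of the threshold, 74 lost and 60 gained a call, and the cause was not tested. The scalings moved the median of all genes by less than 0.1, to −0.06 at most with library totals. Depth limits genes with few reads, such as CDKN1A with 63 reads over the 3 controls.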

Other observations

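The gene lists and the test between the DsiRNAs in this part were planned, and no test here was chosen after its result was seen. Of all 14731 tested genes 61.1% differed between the DsiRNAs. Lists that did not differ as a whole between them held single genes that did, and counts near that share do not set a list apart. Of 30 cholesterol and fatty acid synthesis genes 14 were higher and 11 lower with 13.6 than with 13.8 (camera adjusted p = 0.445), with fatty acid synthase FASN (1.02), which holds AACTGTC, and INSIG1 (0.93) higher and the sterol carrier STARD4 (−0.95) lower. Of 21 unfolded protein response genes 7 were higher and 10 lower (camera adjusted p = 0.563), with the disulfide isomerase PDIA6 (1.86) and the sensor ATF6 (0.77) higher, both of which hold AACTGTC, and SEL1L, part of the pathway that clears misfolded proteins (−0.81), lower. Of 29 integrated stress response genes 8 were higher and 11 lower (camera adjusted p = 0.568), with asparagine synthetase ASNS (−1.17) and CHAC1, which breaks down glutathione (−1.22), lower with 13.6. Of 24 apoptosis regulators 9 were higher and 5 lower (camera adjusted p = 0.563), with the survival genes MCL1 (0.65) and BIRC2 (0.59) higher and the death-promoting genes BCL2L11 (−0.89) and BIK (−2.06) lower with 13.6.

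With DsiRNA 13.8 the 9 measured fibroblast markers stood at 10.9 CPM for LUM, 4.1 for POSTN, 3.7 for THY1, 3.3 for FAP, 2.8 for COL1A1, 1.8 for COL1A2, 0.9 for PDGFRA, 0.7 for COL6A3 and 0.6 for DCN, against 3.1, 0.1, 0.4, 0.3, 1.5, 0.3, 0.4, 0.3 and 0.2 CPM in the controls, and their source was not tested.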
